A study of Rattus norvegicus with 6 samples.

How the data were processed

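Methylated RNA immunoprecipitation sequencing (MeRIP-seq) pulls down fragments of RNA with an antibody against N6-methyladenosine (m6A), the most abundant internal modification of messenger RNA, and sequences them beside an input made from the same RNA. The samples were penile tissue of fetal Sprague-Dawley rats. Their dams received di-(2-ethylhexyl) phthalate (DEHP), a plasticizer with anti-androgenic activity, or the corn oil vehicle by gavage from gestational day 12 to 19, and the fetuses were taken on gestational day 19.5. Titles placed 3 samples in a control group and 3 in a case group. Per the design text of the series, the affected tissue came from male fetuses with hypospadias, a urethral opening on the underside of the penis. Whether each sample is 1 fetus or a pool is not given in the sources used here.

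Per the submitters' processing notes, reads were processed with HISAT2 and the build was Rnor_6.0. The peak caller, its threshold, the gene annotation and whether samples were pooled for calling are not given in the sources used here. The authors' deposited table, as given here, is a single list for the whole series with 5 columns: chromosome, start, end, an Ensembl gene ID and the strand of that gene, per the file headers. Although the name of the sheet speaks of peak counts, the table holds 0 columns of values per sample and no height, enrichment ratio, p-value or q-value. It therefore gives no sequencing depth, and the number of reads behind any interval is unknown. The list carries no mark of the group or sample in which an interval was called. Input libraries and counts per sample were not analysed here.

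The comparison of case with control that was fixed before the data were examined, a quasi-likelihood count test with gene list tests beside it, needs values per sample and could not be run. The lists of genes and cell type markers could not be applied either. The table pairs its 13146 Ensembl gene IDs with no symbols. The RefSeq gene table of assembly GRCr8 used here has 0 entries with an Ensembl ID, so it could not name any of them. The rule fixed for naming genes (the 10 most changed in each direction, up to 4 members of each list, and a few genes fixed by name) thus named none. The 2 gene IDs printed were chosen after their values were seen, for having the most intervals. No genome sequence was used, so exons, introns and untranslated regions were not assigned and sequence motifs were not searched.

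Differences between end and start were whole multiples of 25 bp for most intervals, so starts were read as counting from 0 and are printed counting from 1. Positions are those of the file, which names no build. They were not checked against Rnor_6.0 sequence, and none of the GRCr8 positions was used. As background, chromosome 1 of Rnor_6.0 extends well past 260249035, the highest interval end on that chromosome in the file. The highest ends on chromosomes 2 (249048070) and 10 (107201929) likewise lie short of its chromosome ends and close to those of the later assembly mRatBN7.2, and the gene IDs, numbered up to 71212, are of the kind that Ensembl gave with that assembly. The positions thus look like mRatBN7.2 rather than the build named in the notes. No sequence of either was used here, so the build is unsettled and the positions should not be placed on Rnor_6.0 without a check.

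All computations were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9. Widths and chromosome shares were taken over distinct intervals. Counts per gene were taken over assignments of an interval to a gene, so an interval assigned to several genes counted once for each. A width was called whole-step if it was an exact multiple of 25 bp. In genes with 2 or more intervals the 5'-most and 3'-most intervals were compared within the gene, by the exact two-sided binomial test of discordant genes. In genes with 3 or more, each interior interval's midpoint was placed between the midpoints of the outermost intervals (0 at the 5' end, 1 at the 3' end), and the mean per gene was compared with 0.5 by a two-sided sign-flip permutation test. X-linked and autosomal genes were compared by a two-sided permutation test of gene labels. Permutation tests used 100000 resamples, 95% intervals of means and medians came from 2000 bootstrap draws of genes or intervals, shares have Wilson intervals, and the 5 tests were adjusted together by the Benjamini-Hochberg method. These tests and their alternatives were chosen after the table was seen to hold positions only. The unit of each test is a gene. Genes of 1 list are not independent replicates, so the p-values and intervals describe this list and carry nothing about the spread between animals.

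The position test, the comparison of whole-step widths between the ends and the X comparison were run on simulated data. The permutation tests used fewer resamples there than in the main run. With strands drawn at random, the position test called 2 of 20 draws at 0.05. The 95% bootstrap interval of the whole-step difference excluded 0 in 0 of 20 draws. With gene counts shuffled, the X comparison called 2 of 20 draws at 0.05. The binomial tests themselves were not simulated, nor were the comparisons of 50 bp widths and of the wider end. With 4500 simulated genes of true mean position 0.55, the position test called 20 of 20 draws and the 95% interval held the true mean in 18. That mean was set near the one found in the list, and gene positions were drawn directly and independently. Those draws therefore do not check the placing of intervals or the structure of this list.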

Results

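The study set out to profile m6A across the transcriptome of fetal rat penile tissue in hypospadias. Samples were 3 from control fetuses and 3 from case fetuses, with maternal DEHP or corn oil as the exposure. The deposited table, as given here, was a list of m6A intervals for the whole series with the gene assigned to each. It held no value for any of the 6 samples. The difference between case and control, which the design implies, was therefore not measured here for any gene or interval, and no gene can be said to have gained or lost m6A signal. The following describes the intervals themselves, over both groups. Presence in the list does not tell in which group, or in how many samples, an interval was found.

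The list held 29268 distinct intervals assigned to 13146 genes, by Ensembl ID, on all 20 autosomes, X, Y and the mitochondrial genome. No distinct interval overlapped another. Genes on the plus strand took 16104 of the 31999 assignments (50.3%). Chromosome 1 held the most intervals, 3764 or 12.9% of the total, followed by chromosome 10 with 2408 (8.23%) and chromosome 3 with 2127 (7.27%). The Y chromosome held 10 intervals in 5 genes. The mitochondrial genome held 12 intervals in 10 genes, with all 13 assignments to plus-strand genes. Of all intervals, 26755 (91.4%) were assigned to a single gene. The other 2513 (8.59%, 95% Wilson interval 8.27 to 8.91) were assigned to between 2 and 8 genes. Among these shared intervals, 1833 (72.9%, 95% Wilson interval 71.2 to 74.6) were assigned to genes on both strands, so the list alone does not tell which of the overlapping genes carried the m6A signal there.

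Intervals were mostly short. The median width was 250 bp (95% bootstrap interval 250 to 275), with quartiles of 150 and 525 bp. Widths that were whole multiples of 25 bp made up 23653 intervals (80.8%), with a median of 225 bp. The other 5615 intervals (19.2%) had a median of 1718 bp. Of the 4062 intervals wider than 1000 bp, 85.5% were of this second kind, and of the 888 wider than 10000 bp, 96.2%. Start to end distances are genomic and may include introns, which were not assigned. A distance of this size should therefore not be read as a length of methylated RNA. The widest interval reached 448057 bp, on chromosome 6 from 3182838 to 3630894 in the positions of the file. Among whole-step widths the largest was 102325 bp. The most frequent width was 175 bp, with 3075 intervals (10.5%), against 1179 of 150 bp and 1370 of 200 bp. The narrowest width, 50 bp, was the next most frequent with 2150 intervals (7.35%).

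**Figure D1:**
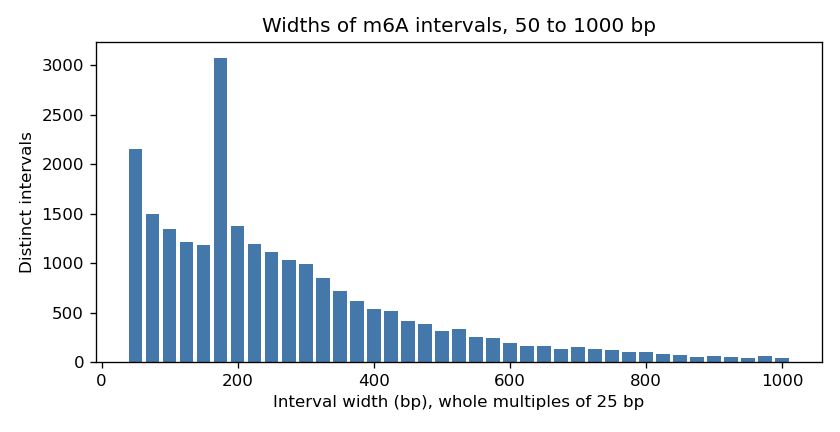
Number of distinct m6A intervals (vertical axis) at each width from 50 to 1000 bp that is a whole multiple of 25 bp (horizontal axis, bp), over the whole list. Bars are counts without error; the bar at 175 bp stands at 3075, above its neighbours at 1179 and 1370.

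Most genes in the list held more than 1 interval. A single interval was listed for 5199 genes (39.5%), and 7947 genes (60.5%) held 2 or more. The mean was 2.43 intervals per gene (SD 1.97, n = 13146 genes), with a median of 2. The 1315 genes with the most intervals, 10% of all, held 28.1% of assignments, and 103 genes had more than 10 intervals each. Neighbouring intervals of a gene were a median of 425 bp apart, with quartiles of 125 and 5461 bp. Of the 18853 neighbouring pairs, 4349 (23.1%) were at most 100 bp apart. Starts of neighbours up to 200 bp apart lay a whole multiple of 25 bp from each other in 87.7% of 6857 pairs. The share was 80.2% for gaps over 200 and up to 1000 bp, 27.6% for gaps over 1000 and up to 5000 bp, and 4.28% beyond that, where chance gives 4%.

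ENSRNOG00000063070, on the plus strand of chromosome 18, held the most intervals. Its 51 intervals lay between 29494054 and 29649078, a span of 155 kb, with a median width of 225 bp, and none was shared with another gene. Of them, 44 had whole-step widths and 7 did not. The gene after it, ENSRNOG00000057569 on the plus strand of chromosome 1, held 24 intervals between 205894829 and 205910753, a span of 15.9 kb, all 24 of them with whole-step widths. The window of 1 Mb with the most intervals also lay on chromosome 18, from 29 to 30 Mb, with 136 intervals in 24 genes. Of these, 51 belonged to ENSRNOG00000063070, and the other 85 intervals were assigned to 23 genes. The windows from 9 to 10 Mb on chromosome 7, with 113 intervals in 50 genes, and from 54 to 55 Mb on chromosome 10, with 102 intervals in 48 genes, followed. Among the 2106 autosomal and X-linked windows with an interval, the median was 9 intervals, and the 211 fullest windows held 34.5% of intervals.

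**Figure D2:**
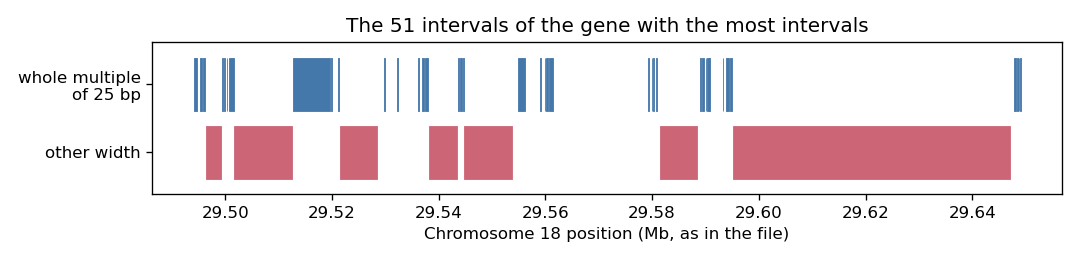
Map of the 51 m6A intervals of ENSRNOG00000063070 on chromosome 18 (horizontal axis, position in Mb as in the file, to scale). The upper row holds the 44 intervals whose width is a whole multiple of 25 bp and the lower row the other 7, which cover most of the wide stretches.

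In genes with 3 or more intervals, interior intervals lay nearer the 3' than the 5' end of the genomic stretch the gene's intervals spanned. This was not seen in those whose intervals all lay on 1 common 25-bp grid. In the 4500 genes with 3 or more intervals, the mean position of interior intervals was 0.553 (95% bootstrap interval 0.545 to 0.562; SD between genes 0.293), where 0.5 is the middle. It was above the middle in 2534 genes and below it in 1956 (sign-flip permutation test, p = 1e-05, the smallest these resamples can give; adjusted p = 1.67e-05). Interior intervals gathered near the outermost intervals of their gene, which set the ends of the span and need not lie at the gene's ends. With the span cut into 10 equal parts, the part at the 3' end held 24.3% of the 10906 interior intervals and the part at the 5' end 17.7%, against 6.57% to 9.77% in each part between. Positions are genomic, with introns included. In genes whose intervals spanned at most 10 kb the mean was 0.519 (95% bootstrap interval 0.509 to 0.529). In the 794 genes whose intervals all lay on 1 such grid (whole-step widths and starts all a multiple of 25 bp apart) the mean was 0.493 (95% bootstrap interval 0.48 to 0.505), which includes 0.5. A break in the grid was read as a sign of an intron, which was not checked against annotation. Whole-step widths reached 102325 bp and the others went down to 55 bp, so this sign is uncertain.

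**Figure D3:**
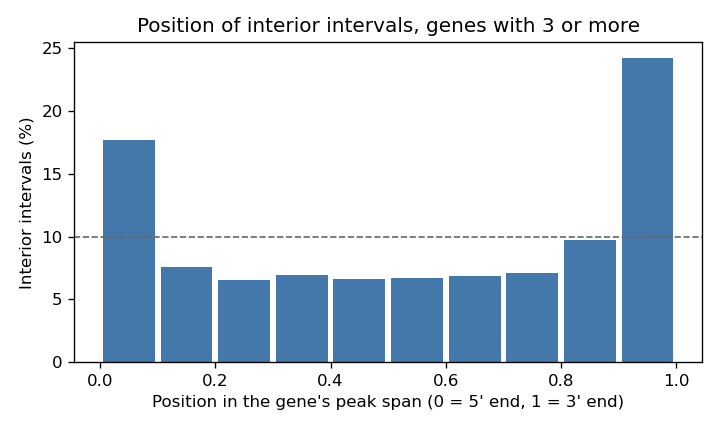
Share of the 10906 interior m6A intervals (vertical axis, percent) in each of 10 equal parts of their gene's peak span (horizontal axis, 0 at the 5' end and 1 at the 3' end) for the 4500 genes with 3 or more intervals. The dashed line marks an even spread of 10%; the 3' part holds 24.3% and the 5' part 17.7%.

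The intervals at the 3' end also differed in form from those at the 5' end of the same gene. In the 7947 genes with 2 or more intervals, the 3'-most interval had a whole-step width in 83.7% and the 5'-most in 73.1%, a difference of 10.6 percentage points (95% bootstrap interval 9.37 to 11.8). Only the 3'-most was whole-step in 1712 genes and only the 5'-most in 868 (exact binomial test, adjusted p = 2.85e-62). The narrowest intervals, of 50 bp, were fewer at the 3' end, where they made up 5.94% against 8.25% at the 5' end (exact binomial test, adjusted p = 3.2e-08). Width itself did not differ by the test over all intervals: the 3'-most was wider in 3861 genes and the 5'-most in 3796 (exact binomial test, adjusted p = 0.465). In genes whose intervals spanned at most 10 kb, the difference in whole-step widths was 5.28 percentage points (95% bootstrap interval 3.69 to 6.80) and that in 50 bp widths -1.25 (-2.40 to -0.12), against -2.32 over all genes. The test of width over all intervals pooled the whole-step widths (median 225 bp) with the others (median 1718 bp), in shares that differed between the ends. With only whole-step intervals kept and the end intervals chosen anew among them, the 3'-most was wider in 58.7% of genes with unequal widths (95% Wilson interval 57.5 to 60.0).

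Genes on the X chromosome held fewer intervals than autosomal genes. The mean was 2.08 intervals per gene (SD 1.46, n = 414 genes) on X and 2.45 (SD 1.99, n = 12717 genes) on the autosomes, a difference of -0.37 (95% bootstrap interval -0.51 to -0.22; permutation test, p = 0.00036, adjusted p = 0.00045). A single interval was listed for 46.6% of X-linked genes and 39.3% of autosomal genes. Means of the autosomes ran from 2.29 on chromosome 4 to 2.73 on chromosome 18, where ENSRNOG00000063070 lies. Without that gene the mean of chromosome 18 was 2.59. The X difference was -0.091 (95% bootstrap interval -0.22 to 0.04) among genes whose intervals spanned at most 10 kb, which includes 0. The span is measured between a gene's own intervals, and the mean number of intervals per gene under this limit was 1.84. Without genes of more than 10 intervals the difference was -0.27 (95% bootstrap interval -0.42 to -0.13). This limit removed no X-linked gene and so lowered the autosomal mean only. Genes without any interval are not in the list, so these means cover only genes with at least 1.

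**Figure D4:**
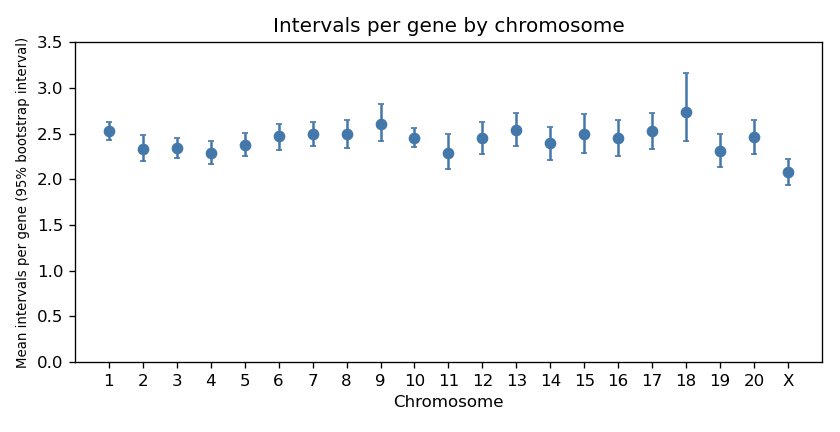
Mean number of m6A intervals per listed gene (vertical axis, with 95% bootstrap intervals over genes as bars) on each autosome and X (horizontal axis). The X mean of 2.08 lies below the lowest autosome mean, 2.29 on chromosome 4.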

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

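The 21 alternatives planned before the data were examined all need values per sample or calls between groups and were not run. No paired analysis was possible because the table holds no values per sample, and leaving out replicates was not possible for the same reason. The 7 alternatives reported here were chosen after seeing the data. Of 47 recomputed values, 36 kept their side of the threshold or, for the median width and mean per gene, stayed within the main 95% interval. The threshold is passed where the 95% interval leaves out the value for no difference, and 0 values reversed past it. The share of genes wider at the 3' end, 50.4% in the main run, did change direction without passing it. This share was 49.2% in genes spanning at most 10 kb, 49.3% without intervals of 50 bp and 49.8% after joining over 100 bp. The median width of 250 bp became 225 bp with whole-step widths alone and 300 bp with intervals up to 100 bp apart joined. The mean of 2.43 intervals per gene was 2.31 with intervals of 1 gene only, 2.31 without intervals of 50 bp, 2.24 with whole-step widths, 2.29 and 2.10 after joining intervals up to 25 and 100 bp apart, 2.34 without genes of more than 10 intervals, and 1.84 in genes spanning at most 10 kb; each alternative removes or joins intervals by construction. The same share rose past the threshold, to 58.7%, with whole-step widths alone, where the end intervals were chosen anew among those kept. The X difference fell short of it, at -0.091, in genes spanning at most 10 kb; the cause was not tested. In the same genes the whole-step difference between the ends was 5.28 and the 50 bp difference -1.25 percentage points, both past the threshold. The mean interior position stayed above 0.5 under all 7 alternatives, from 0.519 in genes spanning at most 10 kb to 0.566 after joining over 100 bp. Depth is unknown, so what it limits could not be assessed.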

Other observations

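These tests were chosen after the patterns had been noticed in the same list. No explanation through exposure or hypospadias was tested, since no value belongs to a group of the study.

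Interior intervals lay nearer the 3' end of their gene's peak span. Assignment to overlapping genes does not account for it, since intervals of a single gene gave a mean position of 0.559 (95% interval 0.55 to 0.569, n = 3650 genes). Nor does the splitting of 1 enriched stretch over gaps of up to 100 bp, since joining such intervals gave 0.566 (95% interval 0.557 to 0.575). Only 23.1% of neighbouring pairs were that close, so splitting over longer gaps was not tested. In the 794 genes with whole-step widths and a common 25-bp phase, read as no sign of an intron, the mean was 0.493 (95% interval 0.48 to 0.505). That reading was not checked against annotation. If it holds, longer introns on the 5' side may produce the shift without any preference of m6A for 3' sequence. The intervals of those 794 genes may all sit in 1 exon. Their mean thus leaves a preference between exons open, which transcript coordinates of the right build would test.

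The 3'-most interval had a whole-step width more often than the 5'-most. The difference was 11.6 percentage points with intervals of a single gene only (95% interval 10.4 to 12.9), which argues against overlapping genes as the cause. Longer last exons are a candidate explanation: in genes with 3 or more intervals the last 2 shared a 25-bp phase in 61.9% and the first 2 in 49.7%, a difference of 12.2 percentage points (95% interval 10.2 to 14.3). Both measures read exon structure from the grid, so they are not independent evidence, and exon lengths were not measured.

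X-linked genes held fewer intervals each. Genes with very many intervals do not account for all of it. Without genes of more than 10 intervals the difference was -0.27 (95% interval -0.42 to -0.13), against -0.37 with them. All 414 X-linked genes stayed under this limit, so it acted on the autosomal side alone. The 20 autosome means averaged 2.45 with an SD of 0.111 and a lowest value of 2.29, so the X mean of 2.08 lay outside the spread between autosomes, a comparison made after these means were seen. Transcript abundance and length on X were not measured and stay open.

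The width of 175 bp was 2.41 times as frequent as the mean of its neighbours, 150 and 200 bp. It made up 11.3% of assignments in genes with 1 interval (95% Wilson interval 10.5 to 12.2) and 10.2% in genes with more (9.84 to 10.6).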
